A study of Mus musculus with 6 samples.

How the data were processed

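The series holds 6 two-colour arrays of mouse (Mus musculus) tissue at 12.5 days post coitum, 3 of pooled whole embryos and 3 of pooled placentas. Per the labels' protocols, embryos of a litter were combined in one tube and its placentas in another, RNA was extracted with TRIzol, and linearly amplified cRNA was labelled with Cy3 and with Cy5. Per the labels, both channels of an array hold RNA of the same source, a design used to measure false differences of the platform. Images were read with Agilent Feature Extraction, per the submitters' processing notes. Its version, its background correction and its dye normalization are not given in the sources used here.

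The authors deposited 1 value per feature and array, used here as a log10 ratio of the channels. The base is not stated: it was taken as 10 because the image software usually writes base 10, and because 4 of the arrays stop at exactly 2 and −2. Neither is the direction stated, so no value is assigned to the brighter dye. If the base were another, folds would change and tests would not. The medians of the arrays lay within 0.0003 of 0, and no value was missing. The limits were reached on embryo arrays 1 and 3 (230 and 43 values) and on placenta arrays 1 and 3 (172 and 160 values). A value at a limit carries no size. Intensities and background of the channels were not used here, so dim and bright features could not be told apart, and a large ratio can come from a dim feature.

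Samples were grouped by the tissue in the labels. The labels do not say that each pool came from its own RNA extraction and labelling, so p-values measure the spread between these arrays, which may be partly technical. No pair of arrays held the same values. The labels number the pools of each tissue 1 to 3. Deviations from the tissue means correlated at 0.141, 0.393 and 0.250 between the embryo and placenta arrays of the same number. Across numbers they correlated between −0.238 and −0.0158. Deviations within a tissue sum to 0, so negative values across numbers follow from the positive ones and are no further evidence. From the same-number values the numbers were taken to pair the arrays. This was decided from all features. Outside the outer frame described below the same correlations were 0.0432, 0.212 and 0.0496, so that much of the pairing rested on the frame.

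Features were named through the platform annotation. Of 22575 features, 4262 had 1 gene symbol (3089 genes), 6822 had several and were left unnamed, and 11491 were not listed. The Entrez ID of 4247 of the 4262 was in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols. That table was used for names only, and positions in the genome are not given. Control features are not marked in the sources used here, so none were left out. Feature IDs run from 1 to 22575 without gaps. Laid out in rows of 215, they put none of the annotated features on the 636 places of the outermost rows and columns, while the other 15 row lengths tried, which divide the IDs evenly and run from 15 to 1505, put at least 19.2% annotated features there. These 636 features are called the outer frame. The layout is inferred and not stated in the sources used here.

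Tests used limma 3.58.1 with statmod 1.5.0 in R 4.3.3, on the values as deposited. One model with a mean per tissue was fitted to all 6 arrays (lmFit and eBayes, 4 residual degrees of freedom per feature), and 4 contrasts were tested: the mean of both tissues against 0, embryo against 0, placenta against 0, and placenta minus embryo. Features with a Benjamini-Hochberg adjusted p under 0.05 over all features were called. For the spread, the share of features beyond 1.5-fold (0.176) and 2-fold (0.301 on the log10 scale) and the robust SD per array were compared between tissues with an exact two-sided permutation test. The 21 gene lists are trophoblast, decidua, yolk sac and liver, erythroid, neural, skeletal muscle, cardiac, cartilage and bone, mesenchyme and matrix, epithelium and keratin, endothelium, immune, ribosomal protein, oxidative phosphorylation, cell cycle, histone, heat shock and stress, glycolysis, housekeeping, imprinted and pluripotency. They were tested with camera (preset correlation 0.01, then an estimated correlation) and with fry, with adjustment over the 21 lists, among features with 1 symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

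The sample groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes, for the contrasts over all arrays and placenta minus embryo, up to 10 called features per direction with the largest ratio, with the same sign on all arrays or with no overlap between tissues, and 1 feature per gene. Where none passed, it takes the 3 with the smallest p. Features without a single symbol fill at most 2 places per direction and are given by ID. It adds the 2 members of each list with the smallest p in each contrast, and the 5 features most often beyond 2-fold. Other list members that passed are named because all such members are given.

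Alternatives were each array's median taken off, arrays scaled to one spread, exact zeros as missing, robust variance moderation, array weights, features of a gene averaged, each array left out, and the pool number as a block (fixed for placenta minus embryo, random by duplicateCorrelation elsewhere). For the lists a rank test was run too. Added after the data were seen were annotated features only, values at the limits as missing or replaced, both arrays of a number left out, multi-symbol features in the lists, the outer frame left out, and the outer frame left out with each array's local median, over a window 11 features wide, taken off. The steps were tested on simulated data made from the spread of the 6 arrays, with 22575 features of which 200 were changed. Over all arrays the model called 85 of 100 features changed by 1.5-fold and 93 of 100 changed by 2-fold, with 10 false calls, and for placenta minus embryo 32 and 68 of 100, with 6 false calls. In simulated noise alone it called 0 and 1. The simulated arrays were independent of each other, so these counts do not cover calls that come from a pairing of the arrays.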

Results

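RNA of mouse whole embryos and placentas, taken at 12.5 days post coitum, was measured on 6 two-colour arrays of 22575 oligonucleotide features that were designed for transcripts of stem cells and early development. Each array carried 1 RNA pool in both channels, labelled with Cy3 in the first and with Cy5 in the second, so that every deposited log10 ratio would be 0 without dye and measurement error. 3 arrays held embryo pools and 3 held placenta pools. Per the labels, pools 1 and 2 of each tissue combined 5 embryos or placentas and pool 3 combined 3. The series asked how often such an array reports a difference that is not there. A ratio above or below 0 here is an error of the measurement of a gene, not a difference in its expression, and the ratios say nothing about which genes embryo and placenta express at different levels. The base of the logarithm and the direction of the ratio are not given in the sources used here, so base 10 was taken from the usual output of the image software, and values are given as above or below 0 without naming the brighter dye. The number of arrays, 6 in all and 3 per tissue, limits the precision of all values.

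The first comparison asked how far the ratios of each array lay from 0 and whether embryo and placenta arrays differed in this. Among features of 1 gene, Sirpa, a receptor of myeloid cells and neurons, lay beyond 2-fold on 5 of the 6 arrays, with both signs in each tissue. Its log10 ratios were −0.676, 0 and the upper limit of 2 on embryo arrays 1 to 3, so that no embryo mean is given, and averaged −0.227 ± 0.517 (SD, n = 3) in placenta. Kidins220, a membrane scaffold protein of neurons, lay below 0 beyond 2-fold on 5 arrays, at −0.441 ± 0.474 in embryo and −0.519 ± 0.109 in placenta (SD, n = 3 each). Its embryo mean includes a value of exactly 0 on embryo array 2. BC052040 lay beyond 2-fold on 4 arrays, on 3 of them at the limit of 2. None of these 3 genes passed the test over all arrays (limma adjusted p = 0.858 for Sirpa, 0.0637 for Kidins220 and 0.176 for BC052040). Features 14620 and 18920, which have no gene name here, lay beyond 2-fold on all 6 arrays. Each was above 0 on 5 arrays and at the limit of 2 on 3 of them, embryo array 1 and placenta arrays 1 and 3, so that no mean is given.

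Of all features, 5.67%, 1.56% and 2.14% lay beyond 2-fold on embryo arrays 1, 2 and 3, and 2.89%, 1.16% and 3.74% on placenta arrays 1, 2 and 3. The mean was 3.13 ± 2.23% in embryo and 2.60 ± 1.31% in placenta (SD, n = 3 each), a difference smaller than the spread between arrays (exact permutation p = 0.8, two-sided; the smallest p that 3 against 3 arrays allow is 0.1). Without embryo array 1 the embryo mean was 1.85%, below that of placenta. Beyond 1.5-fold lay 6.94 ± 4.11% of the features in embryo and 6.80 ± 1.87% in placenta (exact permutation p = 1). The robust SD of the log10 ratios, from the median absolute deviation, was 0.0505 ± 0.0123 in embryo and 0.0468 ± 0.00752 in placenta (exact permutation p = 0.7). On every array, features in the gene annotation lay beyond 2-fold less often than the rest, for example 1.62% against 9.58% on embryo array 1. Of the 11084 annotated features, 0.740 ± 0.787% lay beyond 2-fold in embryo and 0.601 ± 0.280% in placenta (SD, n = 3 each, exact permutation p = 0.9), and without embryo array 1 the embryo mean was 0.298%. With the features laid out by their ID, the 636 features of the outermost rows and columns, none of them annotated, lay beyond 2-fold in 66.4%, 16.5% and 62.1% of cases on embryo arrays 1 to 3 and in 35.2%, 11.5% and 67.0% on placenta arrays 1 to 3. Of these 636, 232 were exactly 0 on embryo array 2 and 184 on placenta array 2, against 51 to 143 on the other arrays. Without this outer frame, which holds features 14620 and 18920, the means were 1.82 ± 1.85% in embryo and 1.57 ± 0.618% in placenta (SD, n = 3 each, exact permutation p = 0.9), with 0.766% in embryo when embryo array 1 was left out too.

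**Figure D1:**
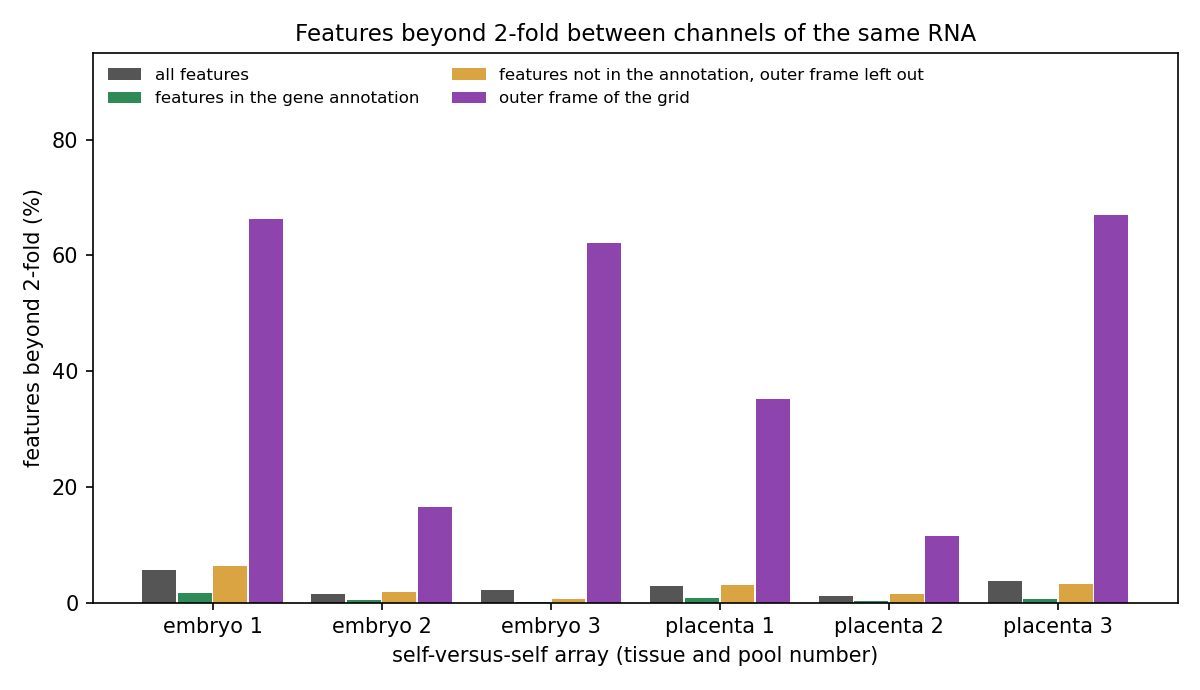
Percent of features beyond 2-fold (vertical axis) on each of the 6 self-versus-self arrays (horizontal axis), 1 bar each for all features, for those in the gene annotation, for those outside the annotation with the outer frame left out, and for the outer frame. The outer frame reaches 67.0% on placenta array 3, whereas the annotated features stay at or below 1.62% on every array.

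The second comparison asked which features had a mean ratio over the 6 arrays that differed from 0, and so would be called although both channels held the same RNA. On the positive side stood Bach2, a repressor in lymphocytes, with a log10 ratio of 0.230 ± 0.0454 (SE, limma adjusted p = 0.0403), Hlf, a transcription factor of blood stem cells, with 0.197 ± 0.0415 (adjusted p = 0.0446), and Tex9 with 0.176 ± 0.0299 (adjusted p = 0.0322). These correspond to 1.70-fold, 1.57-fold and 1.5-fold between the channels. The collagen gene Col6a6 (0.144), the insulin signalling kinase gene Akt2 (0.141), Tsga13 (0.139), Phf21b (0.135) and Nog (0.134), which encodes the bone morphogenetic protein antagonist noggin, also lay above 0 on 6 of 6 arrays. On the negative side, Qser1 had −0.405 ± 0.0652 (adjusted p = 0.0304), Tmed5, a gene of transport between endoplasmic reticulum and Golgi, −0.389 ± 0.0744 (adjusted p = 0.0382) and 4930506C21Rik −0.368 ± 0.0470 (adjusted p = 0.0254), or 2.54-fold, 2.45-fold and 2.33-fold. Resf1 (−0.276), the endocytic receptor gene Lrp1 (−0.263), Ro60 (−0.194), Nol9 (−0.194) and Trappc12 (−0.183) followed, all below 0 on 6 of 6 arrays. On embryo array 3 and on placenta array 3, Nol9 had a value that, within 2e-06, was repeated on 23 features. Among the calls with the same sign on all arrays and no gene name here, 3056 (0.317) and 19687 (0.306) were the farthest above 0 and 8775 (−0.649) and 19781 (−0.588), the latter on the outer frame, the farthest below.

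**Figure D2:**
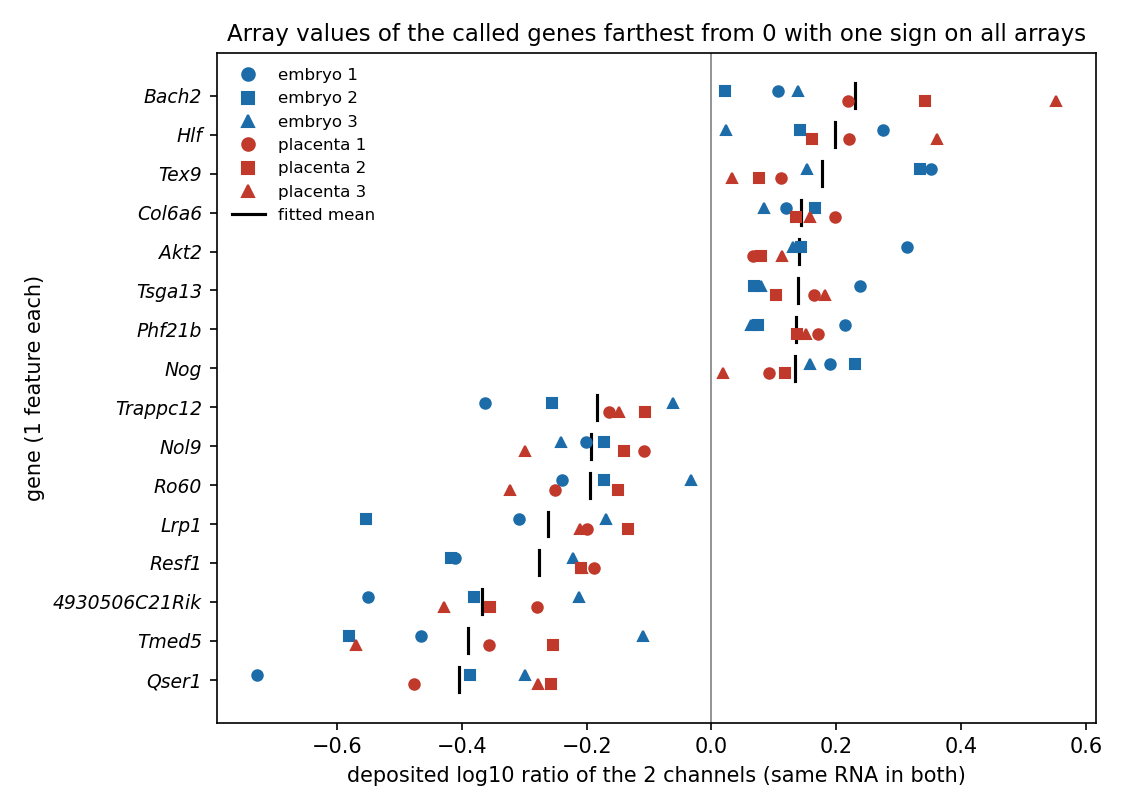
Deposited log10 ratio of the 2 channels (horizontal axis) for the 8 genes farthest above and the 8 farthest below 0 among the calls of 1 gene with the same sign on all 6 arrays, with 1 feature shown per gene (vertical axis), with 1 symbol per array, circles, squares and triangles for pools 1, 2 and 3, blue for embryo and red for placenta, and a black bar at the fitted mean. All arrays of a feature shown lie on the same side of 0, from Bach2 at a mean of 0.230 to Qser1 at −0.405.

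In total 2757 of the 22575 features (12.2%) passed, 1334 above and 1423 below 0 (limma, Benjamini-Hochberg adjusted p under 0.05), and 7917 had an unadjusted p under 0.05. Of the 2757, 2587 had the same sign on all 6 arrays and the other 170 did not, while 2731 lay on the same side of 0 in both tissue means. Of these calls 495 had 1 gene symbol, for 478 different genes, 225 above and 270 below 0. The deviations were small, with a median size of 0.0566, or 1.14-fold, among the calls. Only 313 calls exceeded 1.5-fold and 182 exceeded 2-fold, and 162 of the 182 lay on the outer frame. Without the outer frame 2569 features passed, 1306 above and 1263 below 0, and 2491 of them were among the 2757. Signs recurred across tissues: 6129 features (27.1%) had the same sign on all 6 arrays, where signs independent between all arrays would give 3.125%, and signs fully shared within the 3 same-number pairs 25%. Across features, which are not independent replicates, the embryo and placenta means correlated with Pearson's r = 0.512 and Spearman's rho = 0.525, and with r = 0.346 and rho = 0.510 outside the frame. The count needed the full set of arrays. It was 13 without embryo array 1, 7 without embryo array 2, 1216 without embryo array 3, 0 without placenta array 1, 22 without placenta array 2 and 0 without placenta array 3. Not all of these were among the 2757: all 13, 0 of the 7, 922 of the 1216 and 4 of the 22 were. With the pool number as a random block the same test gave 1682 calls, all of them among the 2757, and 16 of the 44 named calls ended, at adjusted p between 0.0503 and 0.0645, among them those of Bach2, Hlf, Akt2, Tsga13, Tmed5, Lrp1 and Trappc12.

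**Figure D3:**
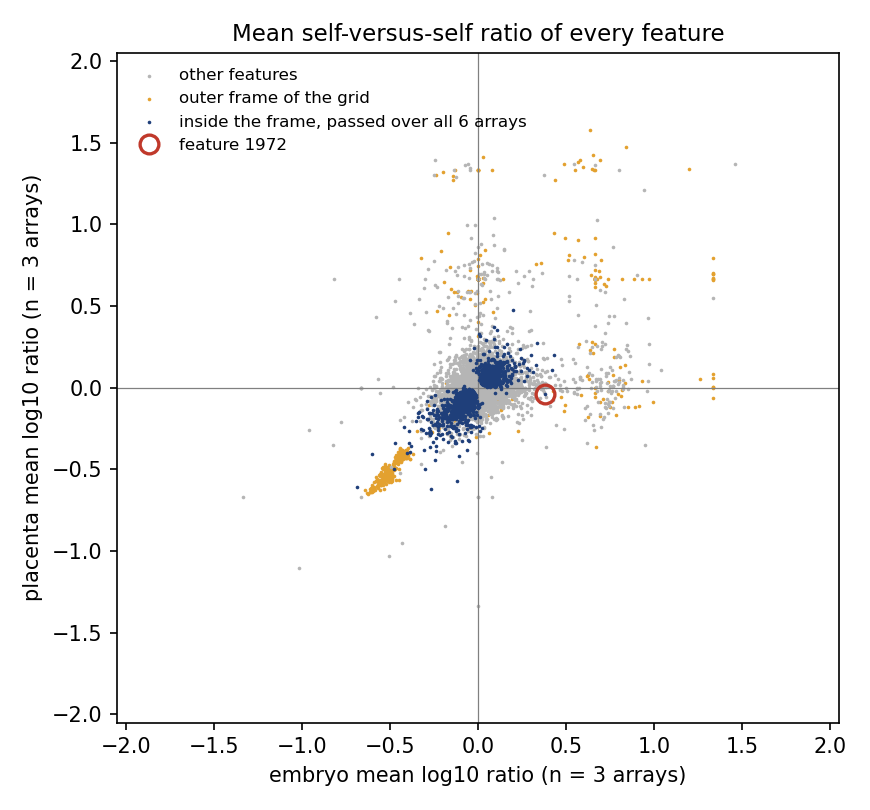
Mean log10 ratio of every feature over the 3 embryo arrays (horizontal axis) and over the 3 placenta arrays (vertical axis), in blue for features inside the frame that passed over all 6 arrays, in orange for the outer frame and in grey for the rest, with feature 1972 ringed. Of the 2590 blue points 148 have a mean over all arrays beyond 1.5-fold and 20 beyond 2-fold, 323 features of the outer frame have a mean below 0 by more than 2-fold, most of them in a tight group, and feature 1972 lies at 0.381 in embryo and −0.0376 in placenta.

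The gene lists, fixed for the tissues of the embryo and placenta and for general cell functions, were described next, counting features of 1 gene. Over all 21 lists 30 of 265 different features passed, 15 above and 15 below 0. Among all features of 1 gene 11.6% passed, so the lists together held no more calls than that share would give. The counts per list are therefore a description and do not set the lists apart from other genes. With the pool number as a random block 11 of the 30 no longer passed, at unchanged means and adjusted p between 0.0501 and 0.0636: Top2a, Tfrc, Pkm, Pgk1, Ncl, Grb10, Ttpa, Kit, Vegfa, Dnajb1 and the Mapt feature above 0. With the outer frame left out and local medians taken off, 12 no longer passed, at adjusted p between 0.0513 and 0.202: Actc1, Cdk1, Tfrc, Pkm, Pgk1, Esrrb, Kit, Vegfa, Dnajb1, Rpl4, the Rpl7a feature at 0.0435 and the Mapt feature above 0. The mean was smaller than before for 11 of these 12, and its median size over the 12 went from 0.0435 to 0.0282. Ttpa did not pass either after the arrays were scaled to one spread (adjusted p = 0.0508). In the ribosomal protein list, 3 of 40 features passed, all above 0, namely Rpl4 (0.0493) and Rpl7a with 2 features (0.169 and 0.0435). The larger Rpl7a value came from placenta, with 0.331 there and 0.00663 in embryo, and was above 0 on 4 of 6 arrays. Of the pluripotency genes, 3 of 18 features passed, all above 0: Tfcp2l1 (0.0692), Esrrb (0.0472) and Kit (0.0419), the stem cell factor receptor gene. The neural list had 1 feature above and 3 below 0 of 22, with Ncam1, the neural cell adhesion molecule gene, at −0.0505 and Lhx9 at −0.0375, whereas Mapt, the gene of the microtubule protein tau, had 1 feature at −0.0970 and another at 0.0270. In the heat shock and stress list, 2 of 18 features lay above 0, Dnaja1 (0.0512) and Slc2a1 (0.0454), and 3 below, Vegfa (−0.0634), Hsph1 (−0.0613) and Dnajb1 (−0.0279). The cell cycle list had 2 of 40 features, both below 0, Top2a (−0.132) and Cdk1 (−0.0344). Some genes had further features that did not pass. For example, only 1 feature passed of the 5 each of Top2a and Rpl4 and of the 3 each of Ncam1, Tfrc and Tmed5. Adjusted over the list alone, 3 ribosomal protein, 5 pluripotency and 4 neural features passed, with 1 of the neural ones above 0, as did 2 above and 5 below 0 of the stress list and 0 of the cell cycle list, in which 12 had an unadjusted p under 0.05.

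The cardiac list had 1 of 7 features, Actc1 (0.0445), the cardiac actin gene, and the skeletal muscle list the same feature together with Ttn (−0.0808), the titin gene, of 8. Of the cartilage and bone list, 1 of 4 features passed, Col9a3 (−0.0934 ± 0.00920 SE, limma adjusted p = 0.0254), and of the mesenchyme and matrix list 1 of 12, Prrx1 (0.0488, above 0 on 5 of 6 arrays). The endothelial list had Sox18 (0.0767) and Flt1 (−0.0677), which encodes a receptor of vascular endothelial growth factor, of 6 features. Flt1 was also the 1 of 9 features that passed in the trophoblast list. The erythroid list had 1 of 5, Tfrc (−0.0440), the transferrin receptor gene, and the yolk sac and liver list 1 of 5, Ttpa (−0.189, below 0 on 5 of 6 arrays), the gene of a vitamin E transfer protein. Of the imprinted genes, 1 of 16 features passed, Grb10 (0.0540). The glycolysis list had Pgk1 (0.0435) and Pkm (−0.0331) of 8, and the housekeeping list Pgk1, Ncl (0.0338) and Eef2 (−0.0647) of 20. No feature passed in limma for the decidua, epithelium and keratin, histone, immune and oxidative phosphorylation lists, of 7, 3, 3, 9 and 12 features, of which 1, 2, 2, 1 and 2 had an unadjusted p under 0.05. Examples are the decidual Timp3 (0.0220), the epithelial Cdh1 (−0.0245), the histone gene Macroh2a1 (0.0388), the leukocyte gene Ptprc (0.107) and the respiratory chain gene Sdha (−0.0211), with adjusted p between 0.0562 and 0.0901, of which Cdh1 and Ptprc passed with annotated features only (0.0442 and 0.0417).

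Adjusted over the list alone, 10 housekeeping features passed (7 above, 3 below 0), 4 of skeletal muscle (3 above, 1 below), 3 each of endothelium (2 above, 1 below) and of yolk sac and liver (1 above, 2 below), and 2 each of cardiac (both above), mesenchyme (both above), erythroid (both below), glycolysis, epithelium and histone (1 on each side in the last 3). On the same count 1 passed of cartilage and bone and 1 of trophoblast, both below 0, and 0 of imprinted, decidua, immune and oxidative phosphorylation, where 3, 1, 1 and 2 had an unadjusted p under 0.05 in limma. None of the 21 lists passed camera, which compares a list with the other features of 1 gene. The lowest adjusted p was 0.301, for the cardiac list, 1 list had an unadjusted p under 0.05, and 0 passed with an estimated correlation. With fry, which tests a list against 0 and not against other genes, 4 lists moved on balance one way: cartilage and bone, immune and ribosomal protein (adjusted p = 0.0239 each) and skeletal muscle (adjusted p = 0.0333). In fry's test of change in either direction 19 lists passed, all but decidua (adjusted p = 0.173) and histone (adjusted p = 0.0613). Median, mean and camera direction differed in sign for the cell cycle, decidua, epithelium, histone, neural, pluripotency and trophoblast lists.

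Within a single tissue few features were called. In embryo alone 1 feature passed, 1972, above 0, with 5573 features at an unadjusted p under 0.05, and the count ranged from 0 to 8 with 1 array left out. It was 0 without embryo array 1 and without any 1 of the placenta arrays, 8 without embryo array 2 and 2 without embryo array 3. In placenta alone limma called 0 features, with 5292 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0506, and it called 26 without placenta array 2. It called 1 with the pool number as a block, 194 after the arrays were scaled to one spread, and 2343 with array weights, which gave placenta array 2 the largest weight, 2.76.

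The last comparison asked whether the self-versus-self deviation differed between placenta and embryo. Only feature 1972, which has no gene name here, passed, with 0.381 ± 0.0200 in embryo and −0.0376 ± 0.00201 in placenta (SD, n = 3 arrays each) and a placenta minus embryo difference of −0.418 ± 0.0143 (SE, limma adjusted p = 0.0124). It lay inside the outer frame. With the pool number as a block no feature passed in limma, with 1577 at an unadjusted p under 0.05. The difference of feature 1972 was then −0.418 ± 0.0152 (SE), with 2 residual degrees of freedom in place of 4 and an adjusted p of 0.670. None passed either without embryo array 1, embryo array 3, placenta array 1 or placenta array 3, whereas 7 passed without embryo array 2 and 19 without placenta array 2, feature 1972 among both. At an unadjusted p under 0.05 there were 1522 features. In the other direction, with at most 2 features without a gene name taken, the smallest p belonged to features 21833 and 7695 and to the ribosomal protein gene Rpl7a. The Rpl7a feature had 0.00663 ± 0.0688 in embryo and 0.331 ± 0.0531 in placenta (SD, n = 3 each) but did not pass (difference 0.324, limma adjusted p = 0.528).

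None of the 265 features of the gene lists passed for placenta minus embryo, and 25 had an unadjusted p under 0.05 in limma. Ascl2, an imprinted gene of the trophoblast lineage, had a difference of 0.0695 ± 0.0131 (SE, limma adjusted p = 0.695), and it was the 1 feature that passed when adjusted over the list alone, in the imprinted and in the trophoblast list, as was Rpl7a in the ribosomal protein list. Of the other 18 lists 0 passed in that count. Among the neural genes Elavl4 had 0.109 and Ncam1 −0.0726, among the cell cycle genes the cyclin gene Ccnd2 0.186, in the cardiac list Ryr2 0.155 and in the skeletal muscle list Tnnt3 0.156, all with adjusted p of 0.695 or higher. In camera 0 of the 21 lists passed and 4 had an unadjusted p under 0.05, with the lowest adjusted p for the cardiac list (0.0675), followed by skeletal muscle (0.0958), imprinted (0.129) and immune (0.234). None passed with an estimated correlation. The cardiac list passed camera without embryo array 3 (adjusted p = 0.0135), without placenta array 1 (0.0460, with skeletal muscle at 0.0424) and without placenta array 2 (0.0218). It did not pass without embryo array 1 (0.141), embryo array 2 (0.411) or placenta array 3 (0.172), nor with the pool number as a block (0.129). In fry the skeletal muscle and immune lists lay on balance higher in placenta (adjusted p = 0.0351 each), and the imprinted, neural, ribosomal protein, mesenchyme and trophoblast lists passed the test of change in either direction (adjusted p between 0.0105 and 0.0268). Median, mean and camera direction differed in sign for the endothelial, glycolysis, mesenchyme, neural, oxidative phosphorylation, stress and trophoblast lists.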

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

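The split test of feature 1972 and the alternatives that leave out the outer frame or both arrays of a number or take off the local level were chosen after the result was seen. Feature 1972, which has no gene name here, stood out because its self-versus-self ratio differed between tissues, with 0.381 ± 0.0200 in embryo and −0.0376 ± 0.00201 in placenta (SD, n = 3 arrays each), a placenta minus embryo difference of −0.418 (limma adjusted p = 0.0124). Its 3 embryo arrays lay above 0 and its 3 placenta arrays below. Of the 10 splits of the 6 arrays into 3 and 3, 5 gave at least as many calls as the 1 of the real split, and the highest of the others gave 8. The 2 splits with 8 calls both put the arrays of number 2 on 1 side, which may point to a structure of the arrays other than tissue, but 8 calls of 22575 features are few and were not set against chance. With 10 splits no share under 0.05 can be reached. Among the 4 splits that part all 3 same-number pairs, the 3 others called 0, and the 6 that part 1 pair called 0 to 8. With the pool number as a block the difference stayed at −0.418, its SE went from 0.0143 to 0.0152 and the residual degrees of freedom from 4 to 2, and with these fewer degrees the adjusted p was 0.670. After the arrays were scaled to one spread the difference was −0.418 with a larger SE of 0.0539. The adjusted p was then 0.418 although the residual degrees of freedom stayed at 4. With the outer frame left out the adjusted p was 0.00927 (−0.418 ± 0.0150 SE), and with local medians taken off as well 0.109, with a smaller difference and a larger SE (−0.378 ± 0.0275). Over the alternatives run for it the adjusted p of feature 1972 ranged from 0.00664, with array weights, to 0.827, without both arrays of number 1. No biological explanation was tested, since both channels held the same RNA.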

How the results depend on the processing

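The alternatives with annotated features only, limits as missing, both arrays of a number left out, and the outer frame and local medians were chosen after the data were seen. Over all arrays 2757 features passed, with 0 to 1216 when 1 array was left out, 1682 with the replicate block, and 0, 20 and 0 without both arrays of number 1, 2 and 3. Among the 2757 were 2 of these 20, 0 of the 7 called without embryo array 2 and 4 of the 22 without placenta array 2. The counts of the other settings stayed within 1.5 times, but not all of their calls were the same features. With annotated features only, 1999 of 11084 passed, 1319 of them among the 2757. After local medians 2807 of 21939 passed, 1797 of them among the 2757. Embryo alone gave 1 call, 0 to 8 with 1 array left out, 0 after scaling to one spread, 2 with zeros missing, 0 with annotated features only, 0, 4 and 0 without both arrays of number 1, 2 and 3, and 0 after local medians. Placenta alone gave 0 calls (limma, 5292 at an unadjusted p under 0.05), 0 to 26 with 1 array left out, 194 after scaling, 2 with zeros missing, 2343 with array weights, 1 with genes averaged, 1 with the replicate block, 160 with annotated features only, 1 with limits missing, 17 without both arrays of number 2, 1 without the outer frame and 6 after local medians. Placenta minus embryo gave 1 call, 0 to 19 with 1 array left out, 0 after scaling, 4 with zeros missing, 0 with the replicate block, 0, 13 and 0 without both arrays of number 1, 2 and 3, and 0 after local medians. Its 1 call with annotated features only was another feature, since feature 1972 is not annotated. With the replicate block, embryo alone kept its 1 call. Gene lists placenta minus embryo passing camera numbered 0 to 2 with 1 array left out. With annotated features only, the share beyond 2-fold was 0.740% in embryo and 0.601% in placenta and the placenta robust SD 0.0376. Fewer arrays leave fewer degrees of freedom, and annotated features only excludes the outer frame and adjusts over fewer features. Every fit with 1 array left out loses the same number of degrees, so this alone does not account for counts from 0 to 1216. The cause of the changes was not tested. Of 44 named calls, 16 over all arrays and feature 1972 ended with the block, 8 ended after local medians (Actc1, Cdk1, Tfrc, Pkm, Pgk1, Esrrb, Rpl4 and feature 1972), 3 after scaling and 24 to 44 with 1 array left out. None changed sign in any setting run. Signal over background was not used here.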

Other observations

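Only the tests of the ratio size of the trophoblast, neural and skeletal muscle lists were chosen before the results were seen; the tests on sign turns, local medians, pairs of features and the repeated value were chosen after. The size of the self-versus-self ratio, as a percentile among all features of an array and without its sign, was set against tissue type, because a transcript that is scarce in a tissue should give a dim feature and a larger error. The neural list lay at a mean percentile of 50.2 on the embryo arrays and 62.6 on the placenta arrays, with 17 of 22 features higher in placenta. Ncam1 went from 22.6 to 87.8, Elavl4 from 33.0 to 89.6 and Mapt from 16.0 to 70.8 in 1 feature each, the largest rise of each gene. Another Ncam1 feature went from 31.9 to 37.4 and another Elavl4 feature from 48.4 to 46.6. Pax6 went the other way, from 89.8 to 33.4. So did 1 feature each of Dcx (85.1 to 43.0), Dlx1 (85.3 to 53.1) and Map2 (62.9 to 48.0). The median shift was 12.7 percentile points, in the direction that scarce neural transcripts in placenta would give, but it did not pass (camera adjusted p = 0.121). Lists for which no shift was predicted moved as far, epithelium by −20.9 (1 of 3 higher in placenta), pluripotency by −19.8 (7 of 18), erythroid by −18.3 (0 of 5), housekeeping by −15.2 (5 of 20) and cardiac by 14.0 (6 of 7). By its size the neural shift therefore does not stand apart, although its unadjusted camera p of 0.00575 was the lowest of the 21 lists. With an estimated correlation its camera adjusted p was 0.689. Scarce transcripts stay open as the source of the neural shift. Skeletal muscle features shifted by a median of 0.614 points (4 of 8 higher in placenta) and trophoblast features by 0.266 (5 of 9 higher in placenta, against the direction of scarce trophoblast transcripts in embryo), both with camera adjusted p = 0.787 and with members on both sides, so these cannot be told apart from no shift. No single feature passed in limma, with 332 at an unadjusted p under 0.05.

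Features with a mean off 0 over all arrays numbered 2757, of which 2587 had the same sign on all 6. The numbers were taken to pair the arrays, and the signs of whole pairs can be turned in 4 ways. As many calls came in 1 of the 4, the real one with 2757, and the highest of the others gave 0. With 4 ways no share under 0.05 can be reached. With signs turned array by array, which takes the 6 arrays as independent, the highest of the other ways gave 1 call. All 15 pairs of arrays, those of different numbers included, correlated with Spearman's rho between 0.250 and 0.522 (0.225 to 0.505 outside the frame). The recurrence therefore did not rest on the same-number pairs alone, but features are not independent replicates and these values give no p. A smooth level across the array as the whole source is argued against: of the 2569 calls made with the outer frame left out, 71.3% (1831, exact 95% interval 69.5 to 73.0%) were still called on the same side after local medians were taken off. This interval takes features as independent. They share the same 6 arrays and neighbouring features may be related, so it may be too narrow. In the 738 others the median size of the mean went from 0.0422 to 0.0308 and the median SE from 0.00783 to 0.00953. Over all 2569 the mean after was a median of 90.5% of the mean before, so a part of the size may depend on place. A property of the transcript as the main source is argued against too. Of 315 pairs of features of 1 gene with at least 1 called, 47.9% lay on the same side of 0 (exact 95% interval 42.3 to 53.6%). Mapt, for example, had 1 called feature on each side. The interval takes pairs as independent, but pairs of 1 gene can share features, so it is too narrow. In all but 17 pairs only 1 feature was called, and the sign of the other may be noise. Of these 17 pairs, 8 lay on the same side. A part from the transcript therefore stays open. Also open and untested is a property of the single feature, such as the sequence of its oligonucleotide. No biological explanation was tested, since both channels held the same RNA.

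On 2 arrays 1 value other than 0 or a limit was repeated over many features (within 2e-06), −0.242 on 23 features of embryo array 3 and −0.299 on 23 of placenta array 3, with 16 features shared, among them Ftl1, Pfdn2 and Nol9. On the other 4 arrays no value was repeated on more than 10. Some of the same features also shared a value on another array. Features 1975, 7342, 13688, 15053 and 18098 were at −0.251 on embryo array 2. Features 11540, 18098 and 19418 were at −0.252 on placenta array 1. A candidate explanation is that both channels were at the top of their scale for abundant transcripts. On the arrays of numbers 1 and 2, which did not pick the features, the 7 at the value on placenta array 3 alone had a median placenta minus embryo difference of −0.130 (−0.263 to 0.0265) and lay lower in placenta in 6 of 7 cases. The 7 at the value on embryo array 3 alone had a median of 0.0672 (−0.00894 to 0.135) and lay lower in embryo in 6 of 7. Of the first 7, 1 was not below 0 on every placenta array, which the explanation would need. Of the 16 features whose symbols all belong to the trophoblast list, 2 were at this value on placenta array 3, against 8 of all 11084 annotated features (Fisher's exact p = 5.44e-05, two-sided), and 0 at that of embryo array 3. This p cannot weigh the explanation, since it rests on 2 features and was not adjusted for the choice of list after the values were seen. It also takes features as independent, which was not checked. With 7 features and no intensities used here, the explanation remains open.

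The outer frame had a regular pattern of its own. Of its 636 features, 323 had a mean below 0 by more than 2-fold, and their median log10 ratio was −0.425, −0.244 and −0.842 on embryo arrays 1 to 3 and −0.257, −0.265 and −1.04 on placenta arrays 1 to 3. The frame held 101, 0 and 26 of the values at the upper limit on embryo arrays 1 to 3 and 122, 0 and 66 on placenta arrays 1 to 3, and 0 at the lower limit. It made up 27.9% to 81.6% of the features beyond 2-fold on an array, lowest on placenta array 2 and highest on embryo array 3.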
